A study of Turicibacter sanguinis with 12 samples.

How the data were processed

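The data are 12 RNA libraries of Turicibacter sanguinis MOL361, a spore-forming gut bacterium, in 4 groups of 3. Per the labels' protocols, cultures were grown anaerobically in Schaedler broth for about 16 h at 37 °C and then held for 4 h with vehicle (control), 200 µM 5-HT (serotonin), 200 µM fluoxetine (an inhibitor of the mammalian serotonin transporter) or both. The concentrations in the combined cultures are not given in the sources used here. Ribosomal RNA was removed with a kit for Gram-positive bacteria and libraries were made with a stranded TruSeq kit, per the labels' protocols. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

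The authors deposited a single table of 3101 rows with raw counts per library, normalized counts (a score), and p-values and q-values for pairs of conditions, per the file headers. The deposited raw counts are whole numbers and were taken as they stand. The authors' normalized counts are rounded scores that equal the raw counts times nearly a single factor per library, between 966 and 2284. The test behind the authors' deposited p-values and q-values, the aligner, the counter, the genome build and the strand setting of the counting are not given in the sources used here. A further 8 columns of values per condition (RPKM and expression) were not used here.

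The rows are 2739 annotated genes with a locus tag, 360 predicted RNAs and 2 rows without a locus tag. The 2 unnamed rows held between 0.000319% and 0.000526% of a library's counts and stayed out of library sizes and tests. Coordinates are those of the deposited table, which names no contig. Of the predicted RNAs, 339 lie on the strand opposite at least 1 annotated gene, and 21 have no annotated gene opposite. No predicted RNA overlaps an annotated gene on its own strand. The 339 are named antisense in the table, and the genes named there matched the coordinates for all 339. An RNA is written here as RNA_ followed by its lower coordinate and is described by the genes on the other strand. The RNAs had a median length of 262 nt, from 10 to 11208 nt, so a short one covers only a small part of the gene named.

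Total counts per library ran from 17596488 to 29439132 with a median of 23887676. Annotated rows received between 189044 and 465567 counts per library, with a median count per gene of 12 to 35, and predicted RNAs received between 17407386 and 29146303, with a median per RNA of 5396 to 10486. Because the annotated rows hold so few of the counts, annotated genes and predicted RNAs were fitted separately, each with its own library sizes. The fit of annotated genes, the gene lists and the rule for named features were fixed before the data were examined. The fit of predicted RNAs, with the same settings, was added once the layout of the table had been seen and before any test was run. Intervals on shares of counts are 95% Wilson intervals and cover counting error only.

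Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, TMM factors) in R 4.3.3, with all 12 libraries in the fit. Rows were kept by filterByExpr, which left 1922 annotated genes and all 360 RNAs. The 6 contrasts tested were each compound and the combination against control, the combination against each compound, and the interaction (whether the log2 effect of the combination differs from the sum of the single effects). P-values were adjusted by the Benjamini-Hochberg method over the features of each fit, with a threshold of 0.05 and no fold minimum. Values are CPM, scaled with the TMM factors of the fit, given as mean ± SD with n = 3, and log2 fold changes are given with their SE. The biological coefficient of variation was 18.1% for annotated genes and 18.9% for RNAs.

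The 28 gene lists were defined as words matched to gene names and products. An RNA belongs to a list if a gene opposite it does. The list of pyruvate metabolism and fermentation also holds other dehydrogenases, the sporulation list holds a dipicolinate synthase, and the list of purine and pyrimidine metabolism holds enzymes that modify uridines in tRNA and rRNA. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and fry beside it. Named features were, per contrast, up to 10 called features in each direction with the largest change, an informative product and no overlap between the libraries of the groups compared, the 5 with the smallest p where none was called, up to 4 called members of each list, and each tested symporter of the neurotransmitter family and each tested bile acid gene. Called features outside this rule are named as such.

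The fit was tested on simulated counts drawn for the contrast of both compounds against control. Among 1922 simulated annotated genes, it called 22.4% of those changed 1.5-fold, 38.8% of those changed 2-fold and 89.4% of those changed 4-fold, and 9 of 1722 unchanged ones. Among 360 simulated RNAs, it called 56.2%, 87.5% and 93.8% at these folds and called 3 of 312 unchanged ones. All simulated groups had the same spread for each row. In the data the median SD over RNAs was 0.201 in the combined group and 0.058 to 0.122 in the others. These rates may therefore not hold for the real contrast.

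Pairs of libraries of a group were compared by chi-square over rows with at least 20 counts. The chi-square per degree of freedom was at least 1.63 for annotated genes and 82.7 for RNAs, so no pair agreed within sampling noise. Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 50 reads in 3 libraries, the replicate number as a block, a fold minimum of 1.5 with glmTreat, limma-trend on the authors' normalized counts plus 1, a fit of only the groups compared, and leaving out each library. No ribosomal RNA or transfer RNA row is named in the table, so the alternative without them had nothing to remove. The alternatives for files with normalized values only did not apply. Contrasts against the same control libraries were set beside 100 simulations of unchanged groups, in which all groups had the same spread for each row. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.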

Results

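Transcripts of T. sanguinis, an anaerobic gut bacterium whose genome encodes a homolog of the mammalian serotonin transporter, were counted after 4 h with 5-HT, fluoxetine, both compounds or vehicle (3 libraries each). Total counts ranged from 17596488 to 29439132 per library. Most of these counts did not lie on the annotated genes. RNAs on the strand opposite annotated genes held 88.4% to 90.9% of each library, and RNAs with no annotated gene opposite held 8.01% to 10.6%. Annotated gene rows held 0.994% (95% Wilson interval 0.991% to 0.998%) in the lowest library, 5-HT+fluoxetine 2, and 1.64% (1.64% to 1.65%) in the highest, 5-HT+fluoxetine 3. These intervals cover counting error only.

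**Figure D1:**
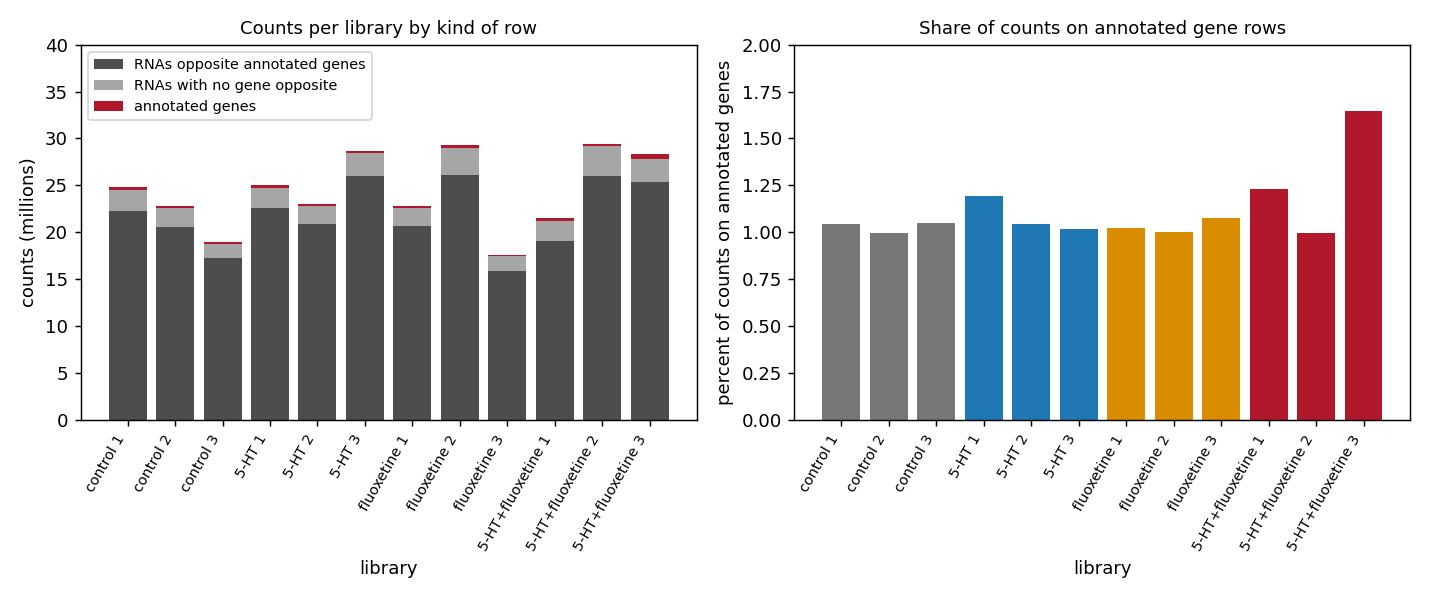
Left, counts per library, stacked by kind of row: predicted RNAs opposite annotated genes, predicted RNAs with no gene opposite, and annotated genes. Right, percent of each library's counts on annotated gene rows; it lies between 0.994% and 1.64%, with 5-HT+fluoxetine 3 the highest.

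Among the RNAs opposite annotated genes were those of the core machinery of the cell. RNA_1555516 lies opposite a run of ribosomal protein genes together with those of the translocase SecY and adenylate kinase, RNA_1550691 opposite the genes of elongation factors G and Tu, and RNA_735682 opposite those of the chaperones DnaK, GrpE and DnaJ. The RNAs opposite ribosomal protein genes numbered 22 and had a median percentile of 89.4 among all predicted RNAs in counts per kb. The 54 annotated rows of ribosomal protein genes had a median percentile of 62.3 among annotated rows. Where an RNA covered at least 90% of a gene, its counts per kb were 5950 times those of the gene's own row at the median of the pairs with a count on the gene's row (136 pairs in all). In the following, values of annotated genes are the counts on the genes' own rows, and values of RNAs are those of the strand opposite the genes named. If the counting used the strand setting opposite to the kit, the annotated rows do not hold the genes' messages. A fall or rise of an annotated row then need not be one of the gene's message.

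Exposure to 5-HT alone was compared with vehicle to ask what serotonin changes in this bacterium. No annotated gene and no RNA passed the threshold. The smallest p-values among annotated genes belonged to a NADH-dependent butanol dehydrogenase (CUW_RS01840, 599 ± 40.2 CPM against 1014 ± 202 in control, SD, n = 3, log2 fold change -0.76, SE 0.173), a subunit of the ATP-dependent Clp protease (CUW_RS06635, -0.89, SE 0.217), the cell division protein FtsE (CUW_RS07380, -0.77, SE 0.197), superoxide dismutase (CUW_RS13225, -0.71, SE 0.190) and the polysaccharide synthesis protein GtrA (CUW_RS10595, 0.91, SE 0.257). The smallest of their adjusted p-values in edgeR was 0.211. Among RNAs they belonged to those opposite fructose-1,6-bisphosphate aldolase of glycolysis (RNA_1162292, -0.28, SE 0.0802), a sucrose transporter subunit of the phosphotransferase system (RNA_1717455, 0.79, SE 0.234), a glycosyl hydrolase (RNA_56773, 0.60, SE 0.184), dephospho-CoA kinase (RNA_492606, 0.21, SE 0.0684) and acid-soluble spore proteins (RNA_2901693, -0.53, SE 0.177), with a smallest adjusted p in edgeR of 0.657.

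RNAs opposite genes of sugar uptake and of the phosphotransferase system, which imports and phosphorylates sugars, were the only list that passed camera with 5-HT, in either kind of row. Of the 8 RNAs of this list, 0 rose, 0 fell and 8 did not pass singly, and 0 were called when adjusted over the list alone. Their median log2 fold change was 0.29, and 7 of 8 were positive, with RNA_1716201 opposite a sucrose transporter subunit at 0.60 (SE 0.276) and RNA_836163 opposite a glucose transporter subunit at -0.22 (SE 0.105). The camera adjusted p was 0.0238 with the preset correlation, and the adjusted p was 0.455 with an estimated correlation. With the replicate number as a block the list did not pass. Some members are neighbouring pieces opposite genes of the same product, such as RNA_1035311 with RNA_1035532 and RNA_836163 with RNA_836435. The members are thus not independent, as the preset correlation nearly takes them to be. The annotated rows of the same list had a median of -0.13 over 23 genes, with a camera adjusted p of 0.277. By edgeR, 0 of 1922 annotated genes were called, with 96 below an unadjusted p of 0.05 where chance gives 96.1, and DESeq2 and limma-trend each called 0. By edgeR, 0 of 360 RNAs were called, with 26 below an unadjusted p of 0.05 where chance gives 18, and DESeq2 and limma-trend each called 0. A fit of the control and 5-HT libraries alone called 7 annotated genes, of which 6 were lower with 5-HT, and leaving out 5-HT+fluoxetine 3 gave 4 genes and 1 RNA. In the authors' deposited table, 50 annotated genes and 21 RNAs had a q-value below 0.05 for this comparison; 43 of the 49 such genes tested here had a negative log2 fold change, and 0 were called here.

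Exposure to fluoxetine alone was compared with vehicle in the same way, and again no annotated gene or RNA passed. The annotated genes with the smallest p-values were the ATP-binding protein of a methionine transporter (CUW_RS08060, -0.57, SE 0.157), ribonuclease Z, which trims tRNA precursors (CUW_RS02330, -0.52, SE 0.161), CTP synthetase (CUW_RS02360, 0.88, SE 0.283), an arylsulfatase (CUW_RS03390, -0.60, SE 0.197) and the stage III sporulation protein E (CUW_RS00820, -1.46, SE 0.502, on 4 to 7 raw counts per fluoxetine library and 6 to 24 per control library), each with an adjusted p of 0.872 in edgeR. The RNAs were those opposite isochorismatase (RNA_2727232, -0.31, SE 0.0681), nicotinate phosphoribosyltransferase of NAD synthesis (RNA_2726461, -0.28, SE 0.0695), fructose-1,6-bisphosphate aldolase (RNA_1162292, -0.29, SE 0.0802), a sucrose transporter subunit (RNA_1717455, 0.84, SE 0.234) and the beta' subunit of RNA polymerase (RNA_1548766, -0.22, SE 0.0641), with a smallest adjusted p of 0.31 in edgeR. No gene list passed camera for either kind of row. By edgeR, 0 annotated genes were called, with 88 below an unadjusted p of 0.05, and DESeq2 and limma-trend each called 0. By edgeR, 0 RNAs were called, with 34 below an unadjusted p of 0.05; DESeq2 called 2, both lower, and limma-trend called 0. Without 5-HT+fluoxetine 3 the count of RNAs was 8, and without control 3 it was 1. The authors' deposited table had 0 annotated genes and 1 RNA with a q-value below 0.05 for fluoxetine.

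Both compounds together were compared with vehicle, and this was the contrast with calls. On the annotated rows, 13 genes fell and 1 rose, which, as said above, need not be changes of the genes' messages. Those that fell included FtsE, an ATPase of the division machinery (CUW_RS07380, plus strand, 1435425 to 1436108, build not given in the sources used here, 290 ± 69.8 CPM against 707 ± 141 in control, SD, n = 3, log2 fold change -1.30, SE 0.201, adjusted p 0.000494 in edgeR), hydrolase Cof (CUW_RS05730, -1.29, SE 0.265), the Clp protease subunit (CUW_RS06635, -1.13, SE 0.217) and superoxide dismutase, which removes superoxide (CUW_RS13225, 380 ± 92.4 against 749 ± 160 CPM, -0.99, SE 0.191). The butanol dehydrogenase CUW_RS01840 (-0.96), the motility protein PilT CUW_RS07100 (-0.89), the tRNA threonylcarbamoyladenosine dehydratase CUW_RS06780 (-0.88), the methionine transporter ATP-binding protein CUW_RS08060 (-0.65), nitroreductase CUW_RS10730 (-0.64) and the membrane protein CUW_RS11725 (-0.59) fell as well. Outside the naming rule, the hypothetical proteins CUW_RS02070 (-0.96), CUW_RS10555 (-0.80) and CUW_RS08265 (-0.76) fell. The row that rose was that of the 50S ribosomal protein L22 (CUW_RS06420, 153 ± 69.6 against 44.1 ± 17.8 CPM, log2 fold change 1.76, SE 0.393, adjusted p 0.0188 in edgeR), which rested on 5 to 15 raw counts per control library and 24 to 67 per combined library.

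Among the RNAs, 13 rose and 11 fell with both compounds, by a fit that shares its estimate of spread over all groups. The median SD over RNAs was 0.201 in the combined group and 0.058 with 5-HT, so these p-values may be too small. With only the groups compared, which leaves fewer degrees of freedom, 0 of the 24 kept their call. The RNA opposite a pair of genes for acid-soluble spore proteins, which bind DNA in dormant spores, and their alpha/beta hydrolase neighbours fell from 10870 ± 2190 to 5363 ± 880 CPM (RNA_2901693, minus strand, start 2903429, stop 2901693, log2 fold change -1.02, SE 0.178, adjusted p 0.0245 in edgeR). The RNAs opposite the ATP synthase genes fell, with log2 fold changes of -0.58 (SE 0.147) for the F1 subunits (RNA_1401099) and -0.55 (SE 0.127) for the F0 subunits (RNA_1399254), as did those opposite lactate dehydrogenase, which turns pyruvate into lactate (RNA_121500, -0.44, SE 0.110), and isochorismatase (RNA_2727232, -0.41, SE 0.0682). RNAs that rose lay opposite the replication genes for DnaA, which starts chromosome replication (RNA_2088727, 0.60, SE 0.153), and the beta subunit of DNA polymerase III, the sliding clamp (RNA_2089253, RNA_2089856 and RNA_2089493, 0.66, 0.54 and 0.49), which are neighbours, and opposite the sigma factor RpoD (RNA_1581850, 0.49, SE 0.124), the ribosomal protein L28 (RNA_859079, 0.72, SE 0.186) and a foldase (RNA_253238, 0.58, SE 0.151). RNAs opposite argS (RNA_2066812, 0.47), the glucose transporter subunit IIA with HPr (RNA_836435, 0.45) and a (p)ppGpp synthetase of the stringent response (RNA_1300617, 0.40) also rose. RNA_2066812 is only 12 nt long and RNA_1300617 only 56 nt. Those opposite a methionyl aminopeptidase (RNA_1567104, -0.45), proline--tRNA ligase (RNA_2276807 and RNA_2275949, -0.40 and -0.35), an RNA pseudouridine synthase (RNA_2362274, -0.36) and peptide chain release factor 1 (RNA_1391892, -0.35) fell. The called features in this contrast had adjusted p-values of at most 0.0435 in edgeR. Outside the naming rule, RNA_1676671 (1.32) and RNA_1966346 (1.10), with no gene opposite, and the RNA opposite an MBL fold protein (RNA_2182874, 0.34) rose, and that opposite an RNA-binding protein (RNA_1388273, -0.32) fell.

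**Figure D2:**
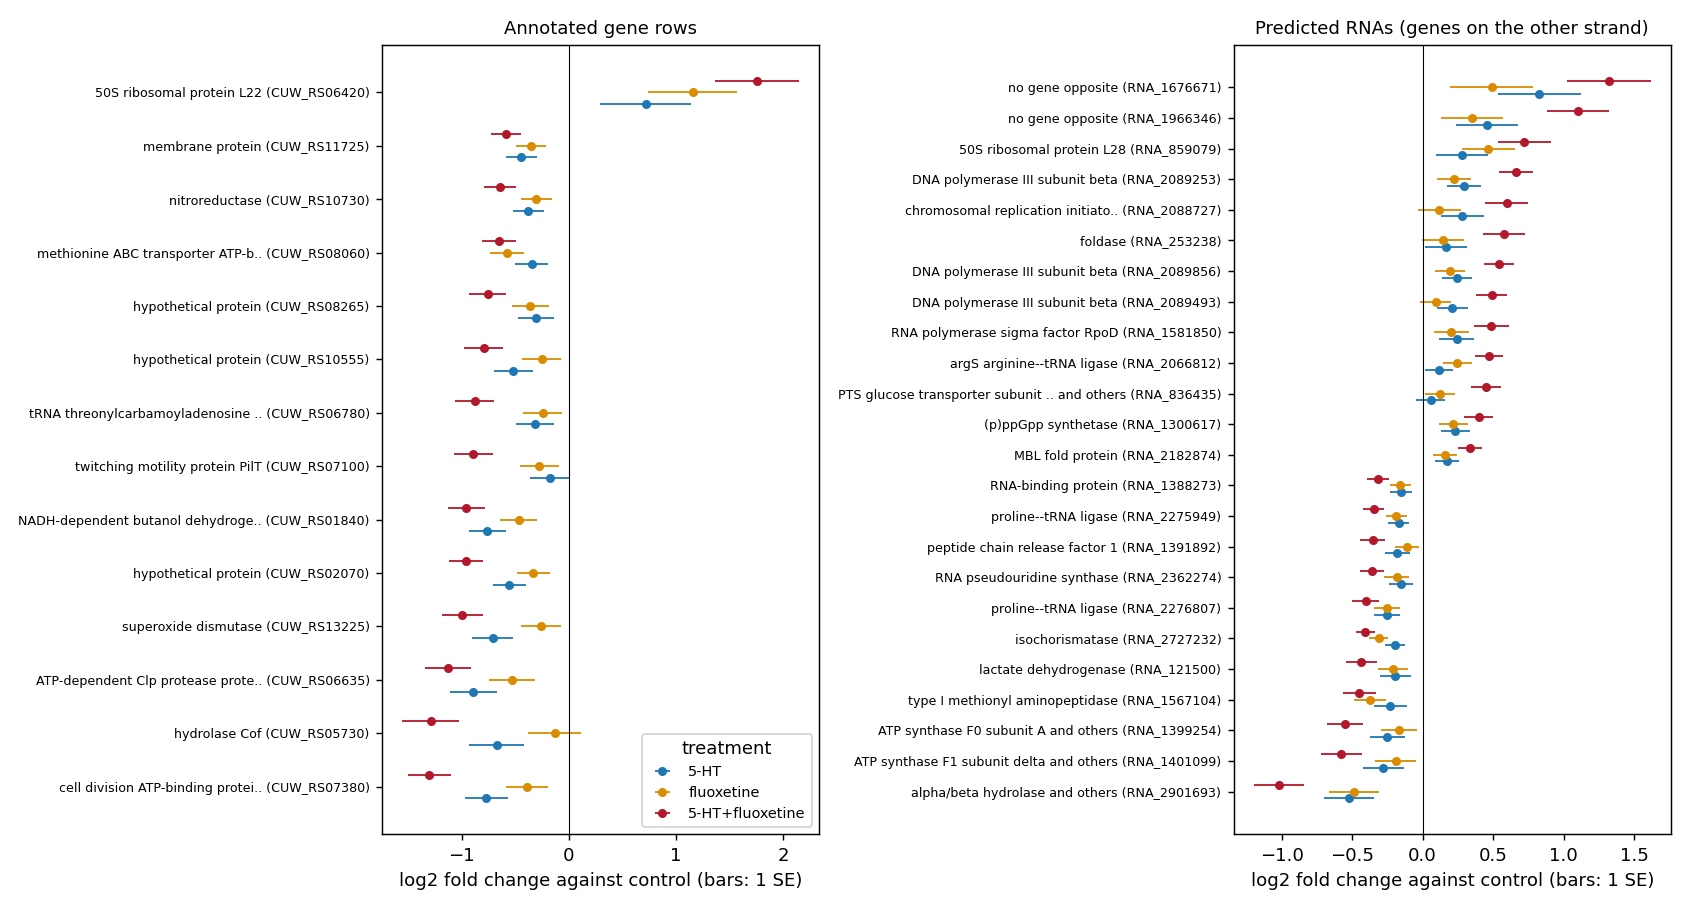
Log2 fold change against control with 5-HT, fluoxetine and both compounds (points, bars are 1 SE, 3 libraries per group) for the 14 annotated gene rows on the left and the 24 predicted RNAs on the right that passed with both compounds. The single compounds lie on the same side of 0 as the combination for all 14 and all 24, which share the control libraries.

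By list, annotated rows of ribosomal proteins had a median log2 fold change of 1.07 with both compounds, and 35 of 36 tested members were positive. Of these 36, 1 rose, 0 fell and 35 did not pass, and 4 were called when adjusted over the list alone, all 4 higher. The camera adjusted p was 3.19e-10 with the preset correlation, and the adjusted p was 0.581 with an estimated correlation of 0.638 between members. The 22 RNAs opposite ribosomal protein genes had a median of -0.11, with 10 positive, 1 risen, 0 fallen and 21 not passed, and a camera adjusted p of 0.598. The mean of these RNAs was 0.01, of the opposite sign to the median and the test. RNA_1555516, which covers L22, stood at -0.40 (SE 0.159, adjusted p 0.109 in edgeR). Annotated rows covered over at least 90% by an RNA on the other strand held 2.27% (95% Wilson interval 2.21% to 2.32%) of the annotated counts in 5-HT+fluoxetine 2 and 1.44% (1.41% to 1.47%) in 5-HT+fluoxetine 3, 0.852% in 5-HT+fluoxetine 1, and 0.59% to 1.41% in the 9 libraries of the other groups.

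**Figure D3:**
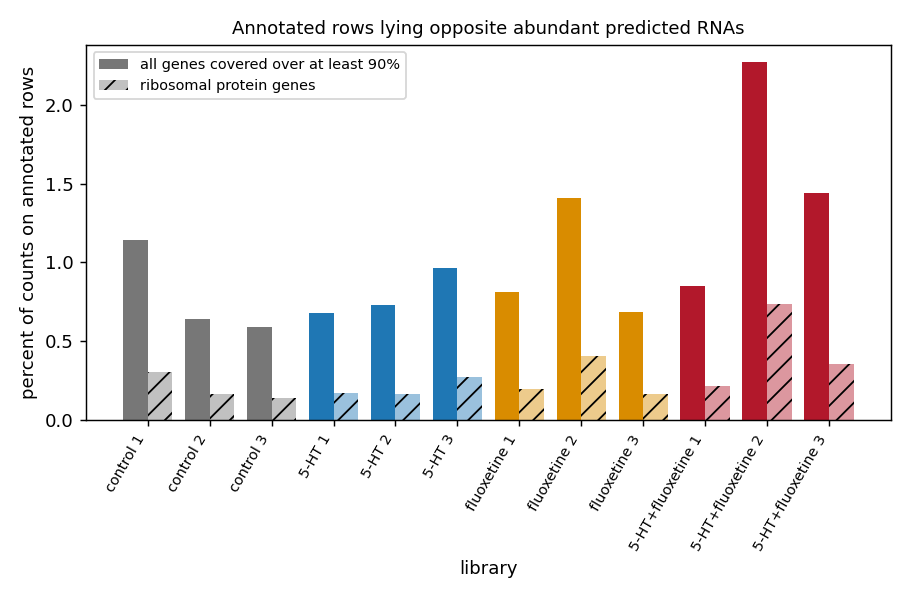
Percent of the counts on annotated rows that fell on genes covered over at least 90% by a predicted RNA on the opposite strand (filled) and on ribosomal protein genes (hatched), per library. The share on covered genes was highest in 5-HT+fluoxetine 2, at 2.27%.

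RNAs opposite genes of purine and pyrimidine metabolism had a median of -0.17 with both compounds, and 17 of 20 were negative; 0 rose, 1 fell and 19 did not pass, and 1 was called when adjusted over the list alone. The camera adjusted p was 0.0249, and the adjusted p was 0.638 with an estimated correlation. The member that fell lies opposite an RNA pseudouridine synthase (RNA_2362274, -0.36, SE 0.0874), an enzyme that modifies RNA rather than making nucleotides. Members that did not pass lay opposite deoxycytidine kinase (RNA_168191, -0.28, SE 0.0884) and adenylosuccinate lyase (RNA_48317, -0.28, SE 0.131). Both RNAs opposite ATP synthase genes fell and 4 of 14 opposite DNA replication and repair genes rose, all 4 at dnaA and its neighbour. In this replication list the median was -0.07 while the mean was 0.13 and camera pointed up (adjusted p 0.586), and 6 RNAs were called when adjusted over the list alone. The 7 annotated rows of ATP synthase genes, by contrast, were all positive with a median of 0.70, and 0 of them passed (camera adjusted p 0.342). Of the 4 RNAs opposite sporulation genes, 1 fell. Among annotated rows, none of 50 tested sporulation genes and none of 6 germination genes passed (camera adjusted p 0.476 and 0.979), and none of 50 genes of purine and pyrimidine metabolism (0.874). In the ABC transporter list 1 of 151 fell, in the redox list 2 of 22, and in the lists of chaperones, fermentation and cell division 1 each (of 12, 30 and 13). The chaperone and redox lists had medians of 0.88 and 0.03, and the fermentation list a median of -0.10 with a mean of 0.06. Of 8 RNAs opposite genes of the phosphotransferase system 1 rose, 6 were called when adjusted over the list alone (5 higher), and the camera adjusted p was 0.0549. Some of these RNAs are neighbouring pieces, as said above.

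In the test of both compounds against control, edgeR called 14 of 1922 annotated genes, with 260 below an unadjusted p of 0.05 where chance gives 96.1, and 24 of 360 RNAs, with 113 where chance gives 18. DESeq2 called 16 genes, all lower, and 78 RNAs, of which 46 were higher, and limma-trend called 12 genes and 3 RNAs. Upper-quartile factors turned the split of called RNAs from 13 higher and 11 lower into 4 higher and 18 lower. The counts moved with single libraries: without control 2 the counts were 2 genes and 0 RNAs, without control 3 they were 8 and 4, without control 1 they were 44 (25 higher) and 62, and without 5-HT+fluoxetine 1, 2 or 3 they were 47, 36 and 16 genes and 15, 105 and 10 RNAs. The RNA count was 3, 4 and 0 without 5-HT 1, 2 and 3, and 4, 13 and 5 without fluoxetine 1, 2 and 3. With only the 6 libraries compared, 4 genes and 0 RNAs passed, and without both 5-HT+fluoxetine 2 and 3, chosen after seeing the data, 1 gene and 0 RNAs did. In the authors' deposited table, 40 annotated genes and 12 RNAs had a q-value below 0.05 for this comparison; 36 of the 38 such genes tested here were positive, and 2 of them and 2 of the RNAs were called here.

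The genes and RNAs called with both compounds were looked up in the single exposures. All 14 genes and all 24 RNAs had the same direction with 5-HT and with fluoxetine (unadjusted p below 0.05 for 10 and 8 genes and 8 and 7 RNAs), but unchanged groups that share the control libraries gave 13.2 and 13.1 of 14 genes and 21.7 and 22 of 24 RNAs on average. Across annotated genes, which are not independent replicates, the log2 fold changes with 5-HT and with fluoxetine had r = 0.579 where unchanged groups gave 0.518 (0.481 to 0.561 over simulations), and a covariance of 0.0645 where they gave 0.0601 (0.052 to 0.0685). Between 5-HT and the combination the genes had r = 0.562 against 0.535 (0.492 to 0.579) and a covariance of 0.083 against 0.0596 (0.0502 to 0.0688), and between fluoxetine and the combination r = 0.602 against 0.523 (0.477 to 0.565) and a covariance of 0.0888 against 0.0597 (0.0505 to 0.0661). Across RNAs r between 5-HT and fluoxetine was 0.798 against 0.499 (0.166 to 0.681 over simulations), and the covariance was 0.0299 against 0.0279 (0.00728 to 0.0586). The RNA covariances with the combination were 0.0481 for 5-HT against 0.0287 (0.00845 to 0.0612) and 0.0543 for fluoxetine against 0.0278 (0.0109 to 0.0687), with r of 0.648 against 0.498 and 0.649 against 0.498. The effect of 5-HT and that of both compounds against 5-HT share the 5-HT libraries with opposite sign, and across RNAs had r = 0.254 against -0.496 (-0.746 to -0.175) and a covariance of 0.0148 against -0.0284 (-0.0719 to -0.0094). Across genes these were -0.228 against -0.495 (-0.545 to -0.452) and -0.0287 against -0.0536 (-0.0649 to -0.0462). The 3 control libraries were not split, since a part would keep fewer than 2, and part of any excess may come from them. The simulated groups all had the same spread for each row. In the data the median SD over RNAs was 0.122 in control, 0.058 with 5-HT, 0.0869 with fluoxetine and 0.201 in the combined group. Values outside the simulated ranges may come from this difference in spread, so no shared response is read from them.

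Both compounds were compared with 5-HT alone to see what fluoxetine changes in the presence of serotonin. No single feature passed. The PTS fructose transporter subunit IIC had the smallest p among annotated rows (CUW_RS11805, 205 ± 70.2 against 66.2 ± 14.7 CPM, log2 fold change 1.66, SE 0.341, adjusted p 0.058 in edgeR), followed by PilT (CUW_RS07100, -0.71, SE 0.184), diacylglycerol kinase (CUW_RS01530, 1.63, SE 0.432), the chaperone HtpG (CUW_RS12455, 1.23, SE 0.333) and the potassium transporter Trk (CUW_RS10575, -0.46, SE 0.130). Without 5-HT+fluoxetine 3 the value of CUW_RS01530 was 0.78, and its row held 7 to 13 raw counts per 5-HT library and 13 to 95 per combined library. The RNA opposite the PTS fructose transporter subunit IIC (RNA_341825) stood at 0.09 (SE 0.195, adjusted p 0.787 in edgeR). Stray reads from the other strand were not tested for the row of this gene or that of HtpG, which also has an RNA opposite. Annotated rows of ribosomal proteins had a median of 1.08, with 36 of 36 positive; 0 rose, 0 fell, 36 did not pass, and 3 were called when adjusted over the list alone. Their camera adjusted p was 1.84e-12, and the adjusted p was 0.537 with an estimated correlation. Chaperones and ATP-dependent proteases had a median of 1.03 with 9 of 12 positive; 0 rose, 0 fell, 12 did not pass and 1 was called when adjusted over the list alone (camera adjusted p 0.00221, and adjusted p 0.533 with an estimated correlation). The 5 RNAs opposite chaperone genes, those of ClpB, GroEL, HtpG, DnaK with GrpE and DnaJ, and trigger factor, had a median of 0.0167 here, which upper-quartile factors turned to -0.091, and a camera adjusted p of 0.87. The RNAs with the smallest p lay opposite dephospho-CoA kinase (RNA_492606, -0.29, SE 0.0685) and the glucose transporter subunit IIA with HPr (RNA_836435, 0.39, SE 0.105). By edgeR, 0 annotated genes and 0 RNAs were called, with 159 and 58 below an unadjusted p of 0.05; DESeq2 called 0 and 2, and limma-trend 0 and 0. Without 5-HT+fluoxetine 1 the count was 12 genes, 10 of them higher, and without control 1, control 3 or fluoxetine 2 it was 1. The authors' deposited table had 317 annotated genes and 78 RNAs with a q-value below 0.05 for this comparison, and 197 of the 313 such genes tested here and 63 of the RNAs were positive.

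Both compounds were compared with fluoxetine alone to see what serotonin changes in the presence of fluoxetine. No single feature passed. FtsE (CUW_RS07380, -0.92, SE 0.203), hydrolase Cof (CUW_RS05730, -1.16, SE 0.266), superoxide dismutase (CUW_RS13225, -0.73, SE 0.192), glutamate--tRNA ligase (CUW_RS06280, -0.50, SE 0.136) and the peptidoglycan transferase CUW_RS09235 (-0.84, SE 0.242) had the smallest p-values among annotated rows, with adjusted p from 0.117 in edgeR. Without 5-HT+fluoxetine 3 the value of CUW_RS06280 was -0.33. Ribosomal protein rows had a median of 0.73 with 35 of 36 positive; 0 rose, 0 fell, 36 did not pass and 0 were called when adjusted over the list alone. Their camera adjusted p was 8.67e-08, and the adjusted p was 0.785 with an estimated correlation. RNAs opposite the DNA polymerase III beta subunit (RNA_2089493, 0.40, SE 0.109) and a ribosome-dependent GTPase (RNA_2063630, -0.37, SE 0.0974) were among those with the smallest p. By edgeR, 0 annotated genes and 0 RNAs were called, with 133 and 63 below an unadjusted p of 0.05, and DESeq2 and limma-trend each called 0 of either kind. Without 5-HT+fluoxetine 2 the count was 22 RNAs, 11 in each direction, and without 5-HT+fluoxetine 1 it was 1 gene. The authors' deposited table had 87 annotated genes and 30 RNAs with a q-value below 0.05, and all 85 such genes tested here and all 30 RNAs had positive values here, against negative ones for the 5 genes with the smallest p.

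The interaction asked whether the combination differed from the sum of the single log2 effects. The smallest p-values belonged to the rows of the ribosomal protein S2 (CUW_RS08225, 2.11, SE 0.548), the PTS fructose transporter subunit IIC (CUW_RS11805, 1.58, SE 0.496), a peptide transporter protein (CUW_RS05780, 1.65, SE 0.522), asparagine synthetase B (CUW_RS09985, 1.08, SE 0.344) and a ferredoxin (CUW_RS12700, 1.13, SE 0.370), each with an adjusted p of 0.984 in edgeR. Without 5-HT+fluoxetine 3 the value of CUW_RS12700 was 0.71. The row of CUW_RS08225 held only 5 to 54 raw counts per library and that of CUW_RS05780 only 6 to 49. The RNAs opposite S2 (RNA_1246787) and the PTS fructose transporter subunit IIC (RNA_341825) stood at 0.14 (SE 0.177) and -0.09 (SE 0.276). Stray reads from the other strand were not tested for the rows of these genes. Ribosomal protein rows had a median of 0.67 with 33 of 36 positive; 0 rose, 0 fell, 36 did not pass and 1 was called when adjusted over the list alone (camera adjusted p 0.00122, and adjusted p 0.646 with an estimated correlation). Chaperone rows had a median of 0.46 with 11 of 12 positive; 0 rose, 0 fell, 12 did not pass and 0 were called when adjusted over the list alone (camera adjusted p 0.044, and adjusted p 0.476 with an estimated correlation), while the 5 RNAs opposite chaperone genes had a median of -0.17 (camera adjusted p 0.768). By edgeR, 0 annotated genes and 0 RNAs were called, with 78 and 23 below an unadjusted p of 0.05; DESeq2 called 0 and 1, and limma-trend 0 and 0. Without 5-HT+fluoxetine 2 the count was 1 RNA. Upper-quartile factors moved the median of all RNAs from 0.02 to -0.14 in this contrast and to -0.10 for both compounds against fluoxetine and against 5-HT, and with the authors' normalized counts these medians were -0.18, -0.15 and -0.11, so the values of RNAs in these 3 contrasts are relative to the TMM scaling.

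The rows of the neurotransmitter symporter family, to which the mammalian serotonin transporter belongs, did not pass in any contrast. CUW_RS07660, named a sodium-dependent serotonin transporter in the table, had 73.5 ± 29.2 CPM in control, 57.4 ± 26.3 with 5-HT, 78.6 ± 7.14 with fluoxetine and 85.7 ± 10.95 with both (SD, n = 3), on 8 to 46 raw counts per library. Its log2 fold changes against control were -0.32 (SE 0.393), 0.11 (SE 0.387) and 0.25 (SE 0.370). The value with 5-HT was -0.73 without 5-HT 1 and -0.08 without 5-HT 2. The other member, CUW_RS05605, stood at 0.22 (SE 0.177), 0.39 (SE 0.178) and 0.32 (SE 0.175), with adjusted p-values of 0.998, 0.972 and 0.447 in edgeR. Its value with 5-HT was 0.12 without control 1 and 0.36 without control 2, and that with fluoxetine was 0.24 without fluoxetine 1. Of 3 choloylglycine hydrolase genes, whose products deconjugate bile acids, CUW_RS11180 was tested and stood at -0.10 (SE 0.371), 0.23 (SE 0.368) and -0.47 (SE 0.376), and CUW_RS05095 and CUW_RS03595 were left untested with mean counts of 1.33 and 3.17. No predicted RNA lay opposite genes of either list. If the counting used the strand setting opposite to the kit, the messages of these genes were not counted in any row. The values above therefore do not show that expression of these genes was unchanged.

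The median SD of log2 CPM over RNAs was 0.201 in the combined group, against 0.058 with 5-HT, 0.0869 with fluoxetine and 0.122 in control, and was 0.238, 0.178 and 0.0946 in the combined group without replicate 1, 2 and 3. Over annotated rows it was 0.318 in the combined group, 0.285 in control, 0.226 with 5-HT and 0.26 with fluoxetine, and 0.288, 0.28 and 0.213 in the combined group without replicate 1, 2 and 3. Of the variance of RNAs, 37.7% lay on a component on which 5-HT+fluoxetine 2 scored 10.1, and 32.2% on a component on which 5-HT+fluoxetine 3 scored -9.37. A few RNAs with no gene opposite were far higher in 5-HT+fluoxetine 2 than elsewhere, such as RNA_1932900 (619 CPM against at most 26.9). How much of its score they carry was not tested.

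**Figure D4:**
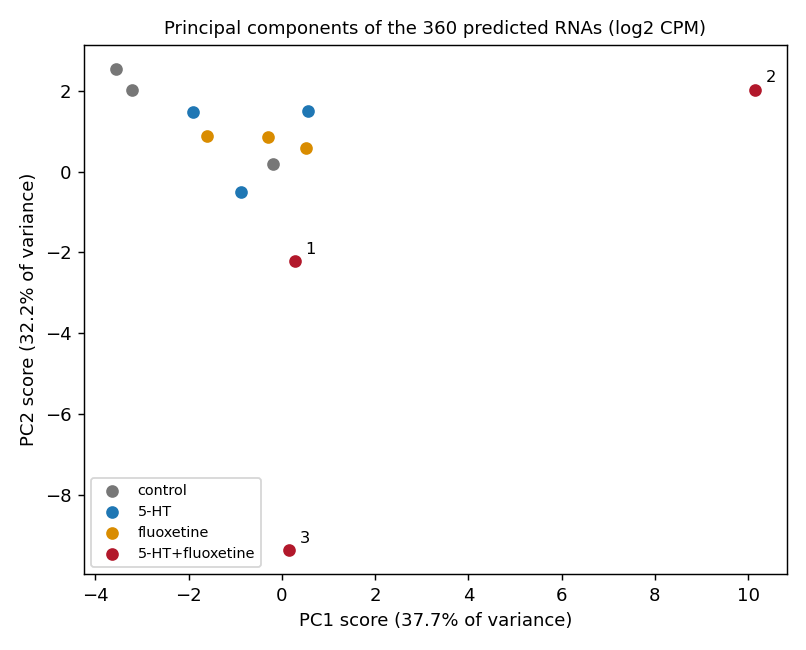
Scores of the 12 libraries on the first principal components of log2 CPM over the 360 predicted RNAs, coloured by group, with the replicate number beside the combined libraries. 5-HT+fluoxetine 2 lies at 10.1 on the axis with 37.7% of the variance, and 5-HT+fluoxetine 3 at -9.37 on the axis with 32.2%. The RNAs with no gene opposite are included.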

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

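The fits of predicted RNAs, the joint fit of both kinds of row and the removal of 2 libraries at once were chosen after seeing the data. The cause of the changes below was not tested. Fewer libraries leave fewer degrees of freedom, and the fit shares an estimate of spread for each row over all groups. Over RNAs the median SD was 0.058 with 5-HT and 0.201 in the combined group. Of the 24 RNAs called with both compounds, 3, 4 and 0 kept their call without 5-HT 1, 2 and 3. These calls thus depend on libraries outside that contrast. For both compounds against control, the count of annotated genes went from 14 to 24 with no filter (14 kept), 0 with a fold minimum of 1.5, 4 with only the groups compared, 9 with RNAs in the same fit and 1 without both 5-HT+fluoxetine 2 and 3, where the lone library was assumed to vary like the other groups. The count of RNAs went from 24 to 78 by DESeq2 (24 kept), 3 by limma-trend, and 0 with the fold minimum, with only the groups compared and without those 2 libraries. Leaving out single libraries gave 2 to 47 genes and 0 to 105 RNAs. With 5-HT against control, 7 genes passed in the fit of only those groups, and single libraries left out gave 0 to 4 genes and 0 to 1 RNAs. With fluoxetine against control DESeq2 called 2 RNAs, and single libraries left out gave 0 to 8. For both compounds against 5-HT, no filter gave 1 gene, DESeq2 2 RNAs and single libraries left out 0 to 12 genes. Against fluoxetine, no filter gave 2 genes, and single libraries left out 0 to 1 genes and 0 to 22 RNAs. For the interaction, DESeq2 called 1 RNA, the fit without 5-HT+fluoxetine 2 and 3 called 1, and single libraries left out 0 to 1. The other alternatives left each count within 1.5 times its value. An alternative with only the groups compared does not exist for the interaction.

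With an estimated correlation, 0 lists passed in any contrast, against 1, 2, 1 and 2 lists of annotated rows in the contrasts with the combination and 1 list of RNAs each with 5-HT and with both compounds. Fry, which asks whether a list moves 1 way and compares it with no other genes, gave 0 lists of annotated rows, 0 lists of RNAs with 5-HT and 2 with both compounds (sugar uptake and nucleotide metabolism). Same-numbered libraries did not deviate together (r from -0.208 to 0.195 over 18 pairs for annotated rows and from -0.42 to 0.366 for RNAs), so the replicate numbers were not taken to pair the cultures. With the replicate block, 19 genes and 21 RNAs passed for both compounds and 0 in the other contrasts, 1 list passed in the interaction from 2, and the list of RNAs with 5-HT went from 1 to 0.

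No called feature among those named changed sign in an alternative that gave it a value, which was 13 of 14 genes with DESeq2 and with at least 50 reads in 3 libraries, and 22 of 24 RNAs without those that have no gene opposite, an alternative chosen after seeing the data. Uncalled values near 0 did. For CUW_RS11180, limma-trend gave 0.0261 with 5-HT, and single libraries left out gave -0.406 to 0.456 with 5-HT, -0.0698 to 0.781 with fluoxetine and -0.777 to 0.0752 with both compounds. For CUW_RS07660 they gave -0.207 to 0.316 with fluoxetine and -0.0688 to 0.453 with both compounds against control. For CUW_RS05605 they gave -0.163 to 0.0720 for both compounds against fluoxetine.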

Other observations

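The tests on ribosomal protein rows with both compounds and on the spread of the combined libraries were chosen only after the results were seen. RNAs with no annotated gene opposite stood out in 5-HT+fluoxetine 2, and were chosen after their values were seen. RNA_1932900 had 619 CPM there against at most 26.9 in the other libraries, RNA_2367732 had 2375 against 155, RNA_970129 had 4589 against 327 and RNA_2133577 had 6794 against 702. The products of these RNAs are not given in the sources used here, and no biological explanation was tested.

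Between 88.4% and 90.9% of each library's counts lay on RNAs opposite annotated genes. A bound set beforehand went against a counting with the strand setting opposite to the stranded kit: it asked for ribosomal protein rows low among annotated rows, and their median percentile was 62.3, with 59.3% of them in the upper part of the rows, as antisense RNA on top of the usual messages would have it. That bound was wrong in leaving out stray reads from the other strand, since counts per kb of covered rows followed those of the opposite RNA (Spearman's rho 0.668 over 136 pairs, across genes, which are not independent replicates), so by these percentiles the explanations cannot be told apart. In a further test set beforehand, ribosomal protein rows held 0.0151% of their opposite RNA and other covered rows 0.0177%, a ratio of 0.855, where stray reads alone would give a ratio near 1. The opposite strand setting therefore goes with these values, though the sources used here do not state the setting. For antisense RNA on top of the usual messages no ratio was set beforehand, so the ratio of 0.855 does not decide against it. The bound set beforehand for it was met at 59.3%, and that outcome was set aside only after rho was seen. Ribosomal protein rows held no larger share of the opposite RNA than other covered rows did. Over the covered pairs with a count on the gene's row, the RNA had 5950 times the counts per kb of that row at the median.

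The annotated rows of ribosomal proteins had a median log2 fold change of 1.07 with both compounds, though 1 of 36 passed singly and the camera call was lost with an estimated correlation (adjusted p 0.581). More ribosomal protein RNA in these cultures is argued against if the RNAs on the other strand carry the messages, since the 22 RNAs opposite these genes had a median of -0.112 (quartiles -0.205 and 0.144). Other genes covered over at least 90% by an RNA on the other strand moved alike, with a median of 0.982 over 67 genes and 88.1% positive, against -0.03 over 1700 genes with no RNA opposite. Stray reads from the abundant opposite strand may therefore account for the ribosomal protein rows, but only if a larger share of them reached these rows. A steady share would follow the opposite RNAs, whose median was -0.112. Covered rows held 2.27% and 1.44% of annotated counts in 5-HT+fluoxetine 2 and 3. In 5-HT+fluoxetine 1 they held 0.852%, within the 0.59% to 1.41% of the other groups. Why this share differed between libraries was not tested. The chaperone rows, and single named rows with an RNA opposite, were not tested separately for stray reads. An effect of the combined treatment on the ribosomal protein rows themselves stays open only if they are the messages. The share of the opposite RNA they held goes with stray reads but does not decide this.

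Over RNAs, the libraries of the combined group lay far apart, with 5-HT+fluoxetine 2 and 3 differing from the rest of their group by a median absolute log2 difference of 0.224 and 0.293. Without the RNAs that have no gene opposite, the lower of these was 0.215 against at most 0.157 in the other groups. That value was of 5-HT+fluoxetine 2, set against a mean that includes 5-HT+fluoxetine 3, which itself stood at 0.279. Without replicate 3 the median SD of the combined group over all RNAs was 0.0946, against 0.058 to 0.122 in the other groups. The typical RNA opposite a gene thus differed in 5-HT+fluoxetine 3, while 0.215 does not show that it differed in 5-HT+fluoxetine 2. A median can move little when 21 of 360 RNAs are removed, and the principal components were not computed without them. This test therefore cannot say how much of the distance those RNAs carry. Depth alone is argued against, since the libraries of other groups at least as deep as 5-HT+fluoxetine 3, 5-HT 3 and fluoxetine 2, differed from their groups by at most 0.0997. That value was of fluoxetine 2, with 29306137 counts against 29439132 in 5-HT+fluoxetine 2. A response to the treatment that varied between cultures, or handling of single cultures, was not tested and stays open.

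The 6 libraries of a pairwise comparison make 10 splits, too few for a share under 0.05. For both compounds against control the real split called 14 genes and the highest other 12 (1 of 10 splits with as many), and 24 RNAs against 39 in another split (2 of 10). For 5-HT and fluoxetine against control and for both compounds against 5-HT, the real split and the highest other called 0 genes and 0 RNAs. With a real count of 0, 10 of 10 splits have as many by construction, which says nothing about chance. For both compounds against fluoxetine the real split called 0 genes and 0 RNAs and the highest other 18 genes and 0 RNAs. The 18 genes here, and the 39 RNAs against control, show that splits other than the treatments can give as many calls or more. A structure of the samples apart from the groups could give this, as could the unequal spread of the groups under a shared estimate. Neither was tested further. For the interaction the real grouping called 0 genes and 0 RNAs and the highest other 3 genes and 0 RNAs, so the 100 of 100 groupings with as many follow from the count of 0 and decide nothing.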
